A study of Mus musculus with 6 samples.

How the data were processed

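Liver RNA of 3 control and 3 LKO male mice, 1 mouse per array, was analysed from one-colour Agilent mouse expression arrays. Per the labels' protocols, cRNA was labelled with Cy3 from 0.1 µg of total RNA. Per the submitters' processing notes and the file headers, Agilent Feature Extraction 11.5.1.1 made the deposited files. The deposited gProcessedSignal values are signal intensities that the software had background-corrected, per the file headers, and the deposited median foreground and background signals are raw intensities. The deposited quality flags (well above background, saturated, outlier) are other values that the software set. The authors' value table equals the processed signal intensity times 1 constant per array, between 2.08 and 2.48, with a relative deviation of at most 5e-10. Its column medians were 55.3, 62.9 and 61.5 in the controls and 63.7, 59.1 and 62.2 in LKO. It is linear and not centred, runs in the same direction as the signal, and how the authors chose the constants is not given in the sources used here.

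The arrays held 59305 spots of 56605 probes besides control spots, 300 probes being printed 10 times. The files pair probes with accessions and not with gene names, so accessions were matched without versions to a RefSeq table of the assembly GRCm38.p6. Of the probes, 32994 (58.3%) had 1 gene symbol, 0 had several and 23611 had none. They named 22911 genes, 7899 of them with more than 1 probe. The array headers name an earlier build than the table, so no coordinates are printed. The table of 6 columns had 0 columns without a sample.

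The value analysed was log2 of the processed signal minus the array's 75th percentile of it. That percentile lay between 265 and 298 processed signal units. Control spots were left out, as were the 64 to 111 outlier spots per array. Spots of a probe were averaged, and a gene was represented by its probe with the highest mean over all 6 arrays. Of the 79 genes named by the fixed rule given below, 18 had several probes above background, and 0 of these had probes that differed in direction. Genes chosen outside that rule were not checked in this way. A gene was tested if its probe was well above background on all 3 arrays of at least 1 group, with at least 2 values per group, which kept 14171 genes and left out 8740. Where a gene was well above background on no array of 1 group, the change is given as "at least N-fold", the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal well above background and the probe's own.

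Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without a block, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of adjusted p 0.05. Gene lists, 37 of them with 798 entries of which 784 matched a gene on the array, were written before the data were examined, as were the groups, the tests and the rule for named genes. Among them 8 are markers of cell types. They were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists, and again with the correlation estimated and with fry. Camera compares a list with the other genes, whereas fry asks whether a list's genes move one way. Members were also adjusted over the list alone. List names such as SREBP or PPAR targets stand for genes chosen from general knowledge, and several genes are in more than 1 list. For gluconeogenesis, insulin signalling, pericentral, xenobiotic, female-biased, lipoprotein and stellate genes, the median, the mean and the camera direction did not all have the same sign.

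Genes were named by a fixed rule. It took Elovl6, then among genes past the threshold with groups that do not overlap and with a symbol that is not a predicted name, the 12 with the largest increase and the 12 with the largest decrease. With fewer than 12, all were taken and followed by those with the smallest p up to 8 per direction. From each list it took up to 4 members past the threshold, by size, or otherwise the 2 with the smallest p. Not every gene that the rule took is printed. Genes outside the rule are said to be chosen after their values were seen.

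The fit was tested on simulated data, 10 runs with 200 of 14171 genes changed in LKO against control. It recovered 69.9% of genes changed 2-fold, 94.9% changed 4-fold and 98.0% changed 8-fold, and 5.45% of the genes it called were false. The simulated genes were independent, and their spreads were shuffled over genes, so changed genes were no more variable than others. In the real arrays Saa2 (11.1-fold), Saa1 (9.74-fold) and Lcn2 (8.78-fold) missed the threshold. The simulated shares therefore do not tell how many real changes of these sizes were called. A mean of 0.1 lists per run was called with independent genes, a setting without the correlation between genes of real lists.

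Alternatives were quantile normalization, median scaling, normexp with an offset of 50, the authors' value table, no filter on dim probes, a filter requiring all 6 arrays, the mean of all probes, outlier spots kept, eBayes with trend and robust fitting, array weights, the replicate number as a block, each replicate left out and other thresholds. Normexp was planned on mean signals, and median signals were used because the array files used here lack mean foreground signals. Camera was given the array weights or the variance trend where these were the alternative. A slide block was not run because there was 1 slide. The slide column as a covariate, probes without a gene symbol and lists without Elovl6 were added after the files were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.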

Results

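The livers of 6 male mice were profiled, 3 with a liver-specific deletion of Elovl6 (LKO) and 3 floxed controls without it. Elovl6 is the elongase that lengthens palmitate to stearate. All mice had eaten a high-sucrose diet for 14 days and were fasted for 4 hours before the liver was taken. Each liver was hybridized to its own one-colour Agilent array, so n = 3 mice per group throughout. All 6 arrays lay on 1 slide and came from 1 scan. Between 52.1% and 56.6% of the 59305 spots were well above background on an array, and no spot was saturated. The number of arrays limits the precision. The comparison of LKO with control asks which liver transcripts differ on a lipogenic diet when the liver lacks this elongase.

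Elovl6 itself, the targeted gene, was 91.0-fold lower in LKO livers (log2 change -6.51 ± 0.30, SE, n = 3 per group, limma adjusted p = 0.00279). Its log2 change was -5.61 with normexp. Its 1 probe, A_65_P20015, was well above background on all 6 arrays. The processed signals were 6364, 12349 and 6624 in the controls and 62.3, 88.5 and 99.6 in the LKO mice, so every mouse matched its label. An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest p that 3 mice against 3 allow. Where the probe lies relative to the deleted part of the gene was not tested here.

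**Figure D1:**
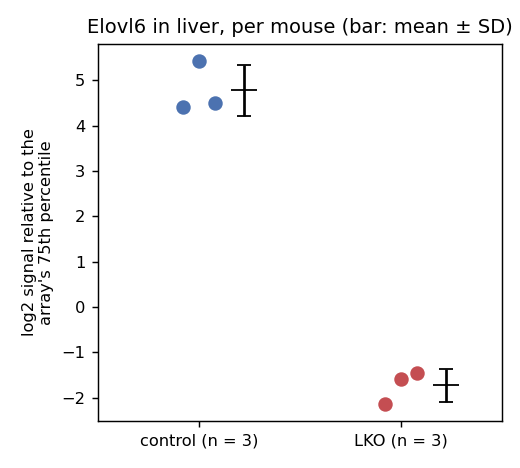
Elovl6 in each liver, as log2 signal relative to the array's 75th percentile, with points for mice and bars for mean ± SD (n = 3 per group). The controls lie between 4.41 and 5.43 and the LKO mice between -2.13 and -1.46.

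Of 14171 genes tested, 2 passed an adjusted p of 0.05, Elovl6 and Usp17la. Usp17la, which encodes a deubiquitinating enzyme, rose 2.62-fold in LKO (log2 change 1.39 ± 0.10, SE, adjusted p = 0.0182). It was well above background on 1 of the 3 control arrays and on all 3 LKO arrays, and its family holds near-identical copies, so which copy was measured is uncertain. The Usp17la call was lost without control replicate 1 (adjusted p = 0.0969), 2 (0.217) or 3 (0.0958) and without LKO replicate 2 (0.0644) or 3 (0.0563). It was also lost with dim probes kept (0.172), with the slide column (0.144) and with normexp (0.0712), where the log2 change was 0.48. Over its alternatives that adjusted p ranged from 0.0119 to 0.217, and the count of genes went from 1 to 16. At an unadjusted p under 0.05 there were 1582 genes, 788 higher and 794 lower in LKO. If no gene differed, 708.55 would be reached by chance on average, and correlation between genes lets such a count vary widely. Other groupings of the same 6 arrays into 3 and 3 gave up to 1175 genes. With the slide column as a covariate, only LKO 1 is set against the controls, so a count from that fit cannot be compared with these. The groups did not overlap for 2454 genes (17.3%), against 10% by chance.

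Several genes came close without passing, all at adjusted p = 0.100. On the higher side these were Saa2 (11.1-fold) and Saa1 (9.74-fold), which encode serum amyloid A proteins and are near-identical copies. Abcb1b, a drug efflux transporter, was 2.13-fold higher, and Rhcg, Hmga2, Ctcflos and Ripply2 were between 1.61-fold and 1.86-fold higher. Abcb1b and Rhcg were each well above background on 1 of the 3 control arrays. The log2 changes were 1.09 for Abcb1b, 0.90 for Rhcg and 0.86 for Hmga2. Over alternatives they went down to 0.38, 0.31 and 0.33. On the lower side, Pdk4, the kinase that inactivates pyruvate dehydrogenase, was 2.62-fold lower, Rdh11, a retinol dehydrogenase, 2.37-fold, and Pgd, an enzyme of the pentose phosphate pathway, 2.21-fold. H2-Q1, Dntt and Reck were between 2.06-fold and 2.21-fold lower. Eya4 was at least 2.49-fold lower, a bound because it was well above background on all 3 control arrays and on none of the LKO arrays. Over alternatives the log2 change of Eya4 lay between -2.12 and -0.54, so this bound did not hold in all of them. Rdh11, Pgd, Pdk4, Dntt and H2-Q1 passed over all genes with normexp and with trend and robust eBayes, and Saa2, Saa1 and Reck passed with normexp.

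Camera called the lipogenic targets of SREBP-1c lower in LKO livers (adjusted p = 1.67e-17), but not with an estimated correlation (adjusted p = 0.256 with an estimated correlation). All 21 measured targets of SREBP-1c in fatty acid synthesis had lower values, with a median log2 change of -1.03, and 15 of them fell when adjusted over the list alone, against 0 over all genes. The members with the smallest p were Elovl5 (2.05-fold lower), which passed over all genes with normexp and with trend and robust eBayes, and Scd1 (2.04-fold lower). Pnpla3 was 6.85-fold lower, a log2 change of -2.78 that lay between -3.34 and -1.71 over its alternatives. Among members chosen after their values were seen, Me1 was 3.34-fold, Acss2 2.86-fold, Fasn 2.75-fold and Acly 2.73-fold lower. Pnpla3 and each of these members passed when adjusted over the list alone. Srebf1, which encodes the transcription factor and was chosen likewise, had a log2 change of -0.16 ± 0.14 (SE) and did not pass.

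Genes of cholesterol synthesis were called lower too (camera adjusted p = 6.51e-20, and adjusted p = 0.318 with an estimated correlation). Of 22 measured targets of SREBP-2, 21 had lower values and 19 fell when adjusted over the list alone, against 0 over all genes. The median log2 change was -0.70. Hmgcs1 (2.42-fold lower) and Dhcr7 (1.65-fold lower) had the smallest p, and over all genes the former passed with normexp and the latter with trend and robust eBayes. Chosen after their values were seen, Mvd was 2.92-fold and Sqle 2.26-fold lower, and Mvk and Ebp were among the members that did not pass.

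**Figure D2:**
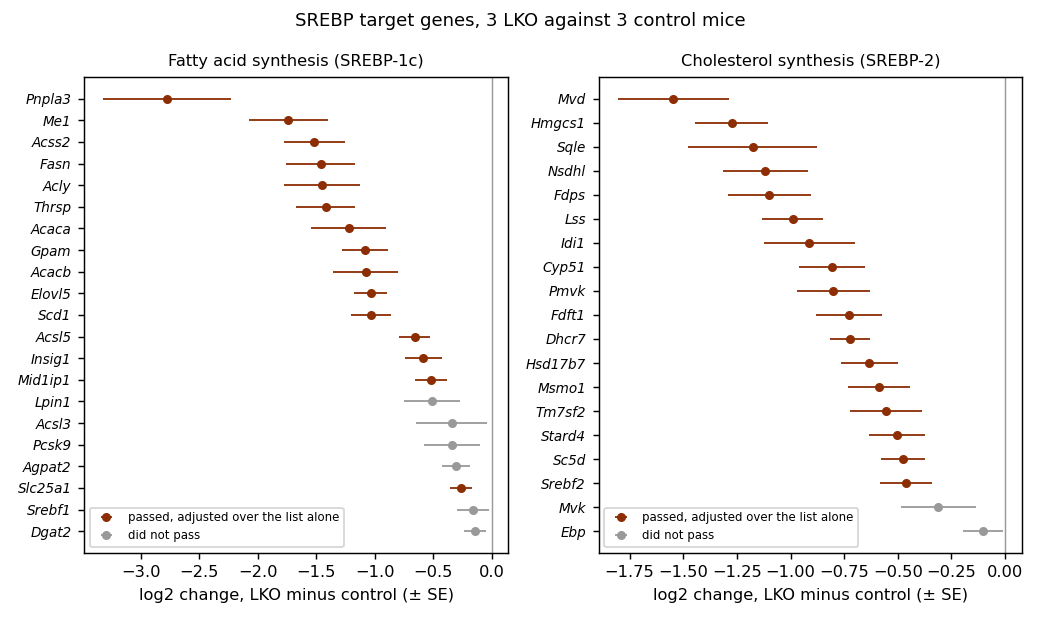
Log2 change (LKO minus control, ± SE, n = 3 per group) of the measured SREBP-1c targets (left) and of 19 of the 22 measured SREBP-2 targets (right), on separate horizontal axes. Dark points passed when adjusted over the list alone, 15 of 21 drawn on the left and 17 of 19 drawn on the right.

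The fatty acid elongation and desaturation list contains Elovl6. Of its 15 measured members, 14 had lower values and 6 fell when adjusted over the list alone, against 1, Elovl6, over all genes. The others that passed within the list were Elovl5, Scd1, Elovl2 (1.39-fold lower), Hsd17b12 and Tecr, both 1.32-fold lower, of which the last 3 were chosen after their values were seen. Hsd17b12 and Tecr act in later steps of the same elongation cycle as Elovl6. Camera gave adjusted p = 2.50e-08 and 2.26e-06 with Elovl6 left out of the lists, and adjusted p = 0.256 with an estimated correlation.

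Other lists of lipid and sugar metabolism were also called lower by camera at its preset correlation, and each lost its call with an estimated one. Among PPAR alpha targets in fatty acid oxidation, 25 of 30 members were lower, and Pdk4, Vnn1 (2.60-fold), Acot2 (log2 change -0.59) and Acot3 (1.55-fold) fell when adjusted over the list alone. None of them passed over all genes, and Acot2 was chosen after its value was seen. Cpt1a, which controls entry of fatty acids into mitochondria and was chosen likewise, had a log2 change of 0.13 ± 0.13 (SE). This list had adjusted p = 7.24e-06, and adjusted p = 0.625 with an estimated correlation. Of 17 PPAR gamma targets in fatty acid uptake, 15 were lower, and Vldlr (2.84-fold), Cd36 (1.52-fold) and Fabp5 (2-fold, chosen after its value was seen) fell when adjusted over the list alone, with 0 over all genes (adjusted p = 9.54e-04, and adjusted p = 0.333 with an estimated correlation). Vldlr was well above background on 2 of the 3 LKO arrays, and its log2 change was -0.52 with normexp. Of 18 lipid droplet genes, 13 were lower, and Pnpla3 and Abhd5 (1.83-fold), which encodes the coactivator of adipose triglyceride lipase, fell when adjusted over the list alone, with 0 over all genes (adjusted p = 0.00175, and adjusted p = 0.256 with an estimated correlation). Of 15 sugar-responsive ChREBP targets, 12 were lower, and Thrsp (2.68-fold) and Pklr (2-fold) fell when adjusted over the list alone, with 0 over all genes (adjusted p = 8.42e-04, adjusted p = 0.100 with the slide column as a covariate, and adjusted p = 0.578 with an estimated correlation).

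Camera called glycolysis (adjusted p = 9.69e-05, and adjusted p = 0.318 with an estimated correlation) and the respiratory chain (adjusted p = 1.56e-07, and adjusted p = 0.396 with an estimated correlation) lower. In glycolysis and fructose metabolism, 15 of 19 genes were lower with a median log2 change of -0.23, and 0 passed adjusted over the list alone or over all genes. Pklr, a pyruvate kinase, was 2-fold and Eno1, an enolase, 1.27-fold lower without passing here. Of 30 respiratory chain genes, 29 were lower by a median of 0.14 on the log2 scale, as in Ndufb8 (1.20-fold) and Sdhd (1.23-fold), and 0 passed adjusted over the list alone or over all genes.

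Genes of acute phase proteins, many of them plasma proteins that the liver makes in inflammation, were called higher in LKO livers by camera (adjusted p = 8.66e-19, and adjusted p = 0.368 with an estimated correlation). All 26 measured members had higher values, with a median log2 change of 0.81, and 20 rose when adjusted over the list alone, against 0 over all genes. Over all genes, Saa2 and Saa1 passed with normexp, and 3 others, Mt2, Mt1 and Lbp, chosen after their values were seen, passed without LKO replicate 1. Chosen after their values were seen, Lcn2, which encodes lipocalin, was 8.78-fold, Saa3 5.93-fold and Orm3 4.33-fold higher, and the haem- and haemoglobin-binding proteins' genes Hpx and Hp were 1.74-fold and 1.62-fold higher. Without LKO replicate 3, Lcn2 was 5.75-fold and Saa3 2.97-fold higher. The mean over the list relative to the control mean was 0.58, 1.31 and 1.72 in the LKO mice and between -0.23 and 0.21 in the controls. With the slide column as a covariate, added after the files were seen, the median was 0.31, since this fit sets only LKO 1 against the controls.

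**Figure D3:**
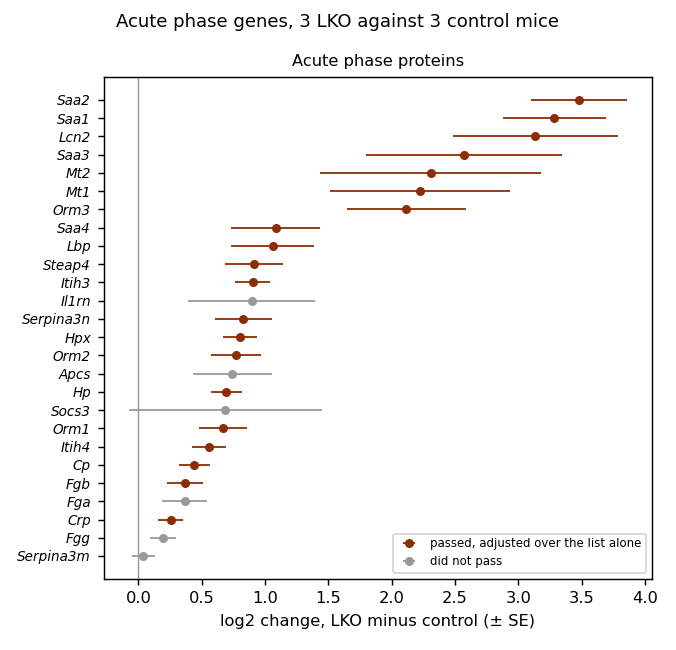
Log2 change (LKO minus control, ± SE, n = 3 per group) of each of the 26 measured acute phase genes. All lie above 0, and dark points are the 20 that passed when adjusted over the list alone.

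Immune cell genes were measured beside these. Of 19 inflammatory cytokine and chemokine genes, Tnf (1.89-fold) and Ccl3 rose and Ccl8 (1.86-fold lower) fell when adjusted over the list alone, with 0 over all genes. Ccl8 was well above background on 2 of the 3 LKO arrays. Ccl3, chosen after its value was seen, was at least 3.00-fold higher, a bound because it was well above background on none of the control arrays. Over alternatives the log2 change of Ccl3 lay between 0.68 and 2.61, so this bound did not hold in all of them. Camera called this list higher (adjusted p = 0.0129, and adjusted p = 0.651 with an estimated correlation). Its call was lost without control replicate 3 (adjusted p = 0.0758), without LKO replicate 3 (adjusted p = 0.312) and with the slide column as a covariate (adjusted p = 0.882). Of 21 Kupffer cell and macrophage markers, 18 had higher values with a median log2 change of 0.20, among them Lyz2 (0.46 ± 0.12, SE) and the scavenger receptor Marco (1.25 ± 0.41, SE), and 0 passed adjusted over the list alone or over all genes. Their adjusted p was 0.00175, and adjusted p = 0.654 with an estimated correlation. This call was also lost without control replicate 3 (adjusted p = 0.0758) and with the slide column (adjusted p = 0.754). In the lymphocyte and neutrophil list, which camera did not call (adjusted p = 0.0701, or 6.59e-04 without LKO replicate 3 and 0.0330 without control replicate 2), S100a8 (5.37-fold), S100a9 (4.63-fold) and Retnlg (2.34-fold) rose and Jchain (1.87-fold lower) fell when adjusted over the list alone, with 0 over all genes. S100a9 and Jchain were chosen after their values were seen. S100a8 and S100a9 were 3.55-fold and 3.08-fold higher without LKO replicate 3 and 8.29-fold and 7.21-fold higher without LKO replicate 1. S100a8, S100a9 and Retnlg mark neutrophils and Jchain marks plasma cells. All 8 erythroid markers had higher values with a median log2 change of 0.25, as in Slc4a1 (0.74 ± 0.29, SE) and Hbb-bt (0.41 ± 0.23, SE), and 0 passed adjusted over the list alone or over all genes. Camera gave adjusted p = 0.0258 for them, and adjusted p = 0.717 with an estimated correlation. The erythroid call was lost without control replicate 1 (adjusted p = 0.202) or 2 (adjusted p = 0.118) and without LKO replicate 1 (adjusted p = 0.462) or 2 (adjusted p = 0.0643), and the globin genes are near-identical copies.

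The genes of endoplasmic reticulum chaperones and the unfolded protein response were called higher by camera (adjusted p = 4.62e-06, and adjusted p = 0.578 with an estimated correlation), with higher values in 21 of 23 members. Derl3, which acts in degradation of misfolded proteins, rose 5.30-fold when adjusted over the list alone, and 0 members passed over all genes. Hyou1 differed by 0.49 ± 0.13 and Hspa5, the gene of the chaperone BiP that was chosen after its value was seen, by 0.27 ± 0.24 (SE) on the log2 scale. The call was lost with the slide column as a covariate (adjusted p = 0.0919). Relative to the control mean, the list mean was 0.18, 0.70 and 0.32 in the LKO mice and between -0.13 and 0.15 in the controls.

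**Figure D4:**
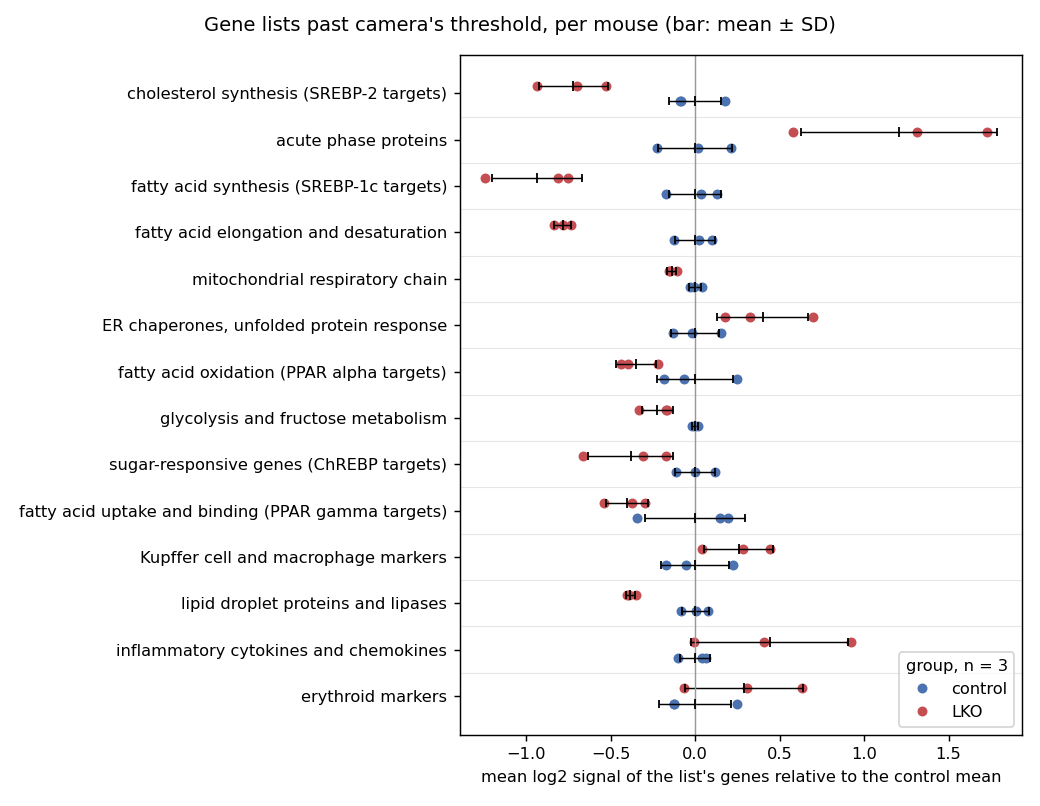
Mean log2 signal of the genes of each list that camera called at its preset correlation, relative to the control mean, with points for mice and bars for mean ± SD (n = 3 per group). The 3 LKO mice lie apart from the 3 controls in 10 of the 14 lists.

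Other liver cell types and functions were not called by camera. Hepatocyte markers had a median log2 change of 0.06 (adjusted p = 0.406), with Ambp and Fgb at 0.22 ± 0.08 and 0.37 ± 0.14 (SE). Endothelial (adjusted p = 0.466, Tie1 -0.18 ± 0.08 and Flt4 -0.27 ± 0.16), stellate (adjusted p = 0.965, Hgf 0.52 ± 0.14 and Des -0.76 ± 0.24), bile duct (adjusted p = 0.812, Krt19 -0.69 ± 0.20 and Pkhd1 -0.42 ± 0.18) and pancreatic or adipose markers (adjusted p = 0.843, Cela2a 0.47 ± 0.22 and Ctrl -0.47 ± 0.43) did not pass, as lists or in any member. Values beside gene names in this paragraph are log2 changes with SE. Periportal genes (adjusted p = 0.0745, with Sds at 0.53 ± 0.17 and Sdhd at -0.29 ± 0.09) had no member that passed adjusted over the list alone, and camera called them with trend and robust eBayes (adjusted p = 0.0466, higher). Of the pericentral genes (adjusted p = 0.451), Cyp1a2 fell 1.37-fold when adjusted over the list alone and Lgr5 was at -0.70 ± 0.20. Fibrosis genes (adjusted p = 0.269, Col4a2 0.28 ± 0.10 and Mmp2 -0.55 ± 0.26) and interferon-stimulated genes (adjusted p = 0.700, Oas2 0.62 ± 0.19 and Cxcl9 -0.43 ± 0.17) had none. Leaving out 1 mouse brought a call for periportal genes (adjusted p = 0.0387 without control replicate 3, higher), fibrosis genes (0.0446 without control replicate 3 and 2.89e-04 without LKO replicate 1, higher) and interferon-stimulated genes (1.16e-04 without LKO replicate 2, lower).

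Further metabolic and regulatory lists were not called by camera. Triglyceride synthesis had adjusted p = 0.0734, and Gpam, the first acyltransferase of the pathway, fell 2.12-fold when adjusted over the list alone, while Agpat2 was 1.23-fold lower without passing. In the NRF2 list (adjusted p = 0.406), Pgd, Tkt (1.44-fold) and G6pdx (4.08-fold, chosen after its value was seen) fell and Gstp1 (1.48-fold, chosen likewise) rose when adjusted over the list alone. Pgd, Tkt and G6pdx are enzymes of the pentose phosphate pathway, which supplies NADPH. Por, the electron donor of cytochrome P450 enzymes, rose 1.89-fold within the xenobiotic list (adjusted p = 0.827), where Cyp3a13 was 1.64-fold higher without passing. Cyp7b1, the oxysterol hydroxylase of the alternative bile acid pathway, rose 2.19-fold within both the bile acid (adjusted p = 0.700) and the male-biased list (adjusted p = 0.112), and C8a rose 1.49-fold within the latter. Cyp8b1 was 1.56-fold lower without passing. Rrm2 fell 1.55-fold within the cell cycle list (adjusted p = 0.780), where Ccne1 was 1.38-fold higher without passing. Vldlr fell within the ATF4 list (adjusted p = 0.812), where Asns was 2.27-fold higher without passing. All these gene calls were adjusted over the list alone, and 0 of these genes passed over all genes. With normexp and with trend and robust eBayes, however, Por and Pgd did pass over all genes. Without 1 mouse, camera called triglyceride synthesis lower (adjusted p = 0.0471 without LKO replicate 1, and 0.0311 with all mice and dim probes kept), male-biased genes higher (0.00857 without control replicate 2 and 0.00455 without LKO replicate 3) and cell cycle genes lower (0.00890 without control replicate 3), where they had been higher on the whole.

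Of the clock genes (adjusted p = 0.633), Cry1 fell 1.55-fold when adjusted over the list alone, with 0 over all genes, and Tef differed by 0.65 ± 0.18 (SE) on the log2 scale. Cry1 and, among insulin signalling genes, Prkce were each well above background on 2 of the 3 LKO arrays. Arntl (-0.93 ± 0.29) and Dbp (0.96 ± 0.34), chosen after their values were seen, did not pass. Of the 17 measured clock genes, 10 were higher and 7 lower. Camera looks for a shift in 1 direction, so it cannot tell such a mixed change from none. No member passed, adjusted over the list alone or over all genes, among gluconeogenesis genes (adjusted p = 0.541, Sds 1.44-fold and Foxo3 1.31-fold higher), insulin signalling genes (adjusted p = 0.907, Ppp2ca 1.16-fold and Prkce 1.35-fold lower), ceramide and sphingolipid genes (adjusted p = 0.580, Ormdl3 1.22-fold lower and Cers4 1.25-fold higher), lipoprotein genes (adjusted p = 0.907, Pltp 2.51-fold lower) or female-biased genes (adjusted p = 0.907, Acot3 1.55-fold and Cyp4a10 2.03-fold lower). Acot3, in 2 lists, passed among the PPAR alpha targets.

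In all, camera called 14 of 37 lists, 5 higher and 9 lower, and 0 with an estimated correlation (lowest adjusted p = 0.256). Fry called 0 lists as well (lowest adjusted p = 0.0576), and no list mean could go below an exact permutation p of 0.1 with 3 mice per group.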

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

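All tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the arrays, and what would decide them was written after the values were seen.

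Probes without a gene symbol were outside the comparison of genes. When the 8272 of them that passed the filter were tested beside the genes, 4 passed an adjusted p of 0.05. Probe A_55_P2139587 was well above background on all 3 control arrays and on none of the LKO arrays, and was at least 33.7-fold lower (limma adjusted p = 6.12e-04), its log2 difference of -7.20 being taken against background. Probe A_55_P2062084 was higher by 5.03 ± 0.30 on the log2 scale (SE, adjusted p = 0.00710), with 2 of 3 control arrays well above background. Probe A_66_P126852 was higher by 3.64 ± 0.25 (adjusted p = 0.0119), with 1 of 3. Probe A_55_P2041184 was well above background on none of the control arrays and on all 3 LKO arrays, and was at least 3.11-fold higher (adjusted p = 0.0119), its log2 difference of 3.29 being taken against background. The genes that these probes measure were not identified here.

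SREBP target genes were lower in LKO, with a median log2 change of -0.72 over the 43 genes of both lists. Fewer hepatocytes in the LKO samples would lower hepatocyte markers as much, but these had a median change of 0.0579 (95% bootstrap interval over members -0.05 to 0.13), which argues against that cause. The interval does not measure the spread between mice, and whether an acute phase response raised some of these markers was not tested. Less recent feeding could lower the SREBP target genes and would raise PPAR alpha targets. Their list mean differed by -0.35, below every control in all 3 LKO mice, against a control SD of 0.22, but an acute phase response could lower these targets as well, so feeding stays open. The slide column stays open too, although LKO 1, the only LKO array in the controls' column, lay 0.70 below the lowest control and the median was -0.72 with the column as a covariate, since both values rest on that 1 LKO array.

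Acute phase genes were higher in LKO, with a median log2 change of 0.81. A single inflamed LKO mouse would leave the other LKO mice among the controls, but the lowest LKO list mean exceeded the highest control by 0.37, more than the control SD of 0.22. More macrophage RNA would raise macrophage markers as much, but their median change was 0.20 (95% bootstrap interval over members 0.14 to 0.29). The interval does not measure the spread between mice. Relative to the control mean, the mean of these markers was 0.04, 0.29 and 0.45 in the LKO mice and -0.05, 0.22 and -0.17 in the controls. The comparison bears on the list as a whole, and macrophage RNA as a source of single members was not tested. RNA of neutrophils, whose markers S100a8 and S100a9 rose adjusted over the list alone, stays open as a source of part of the change, such as that of Lcn2, and was not tested. A response to the genotype stays open too, as untested. The slide column also stays open. Relative to the control mean, the list mean was 0.58 in LKO 1, the only LKO array in the controls' column. It was 1.31 in LKO 2 and 1.72 in LKO 3. With the column as a covariate the median log2 change was 0.31, which rests on LKO 1 alone.

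LKO 1 lay between the controls and the other LKO mice. On the first principal component, with 37.4% of the variance, it was at 2.36, the controls between -18.4 and -12.7 and LKO 2 and LKO 3 at 22.1 and 23.9. Incomplete deletion could give this, but Elovl6 was lowest in LKO 1, differing from the lower of the other LKO mice by -0.55 on the log2 scale. The slide column cannot be told apart from a real difference of this mouse. On an axis fitted without the array placed, with the control mean at 0 and the mean of the other LKO mice at 1, LKO 1 was at 0.45, controls at most at 0.34 and LKO 2 and LKO 3 at 0.85 and 0.77.

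The 10 ways to split the 6 arrays into groups of 3 are too few for a share under 0.05. In 1 of them, the real one, 2 genes passed, and the highest of the others had 1. At an unadjusted p under 0.05 the real split had 1582 genes, and the highest of the others, control 1, LKO 2 and LKO 3 against the rest, had 1175. LKO 2 and LKO 3, the only arrays outside the controls' slide column, lie on the same side in it. For gene lists called by camera, 2 of the 10 splits gave as many as the real 14, and the highest of the others also gave 14. That split set control 1, LKO 1 and LKO 2 against the rest and follows neither the slide column nor the slide position. Camera at its preset correlation thus called many lists in groupings that mix the genotypes. Each such grouping is still uneven in genotype, so part of any genotype difference remains in it. These counts are therefore not a measure of false calls.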

How the results depend on the processing

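The slide column as a covariate, probes without a gene symbol and lists without Elovl6 were added after the data were seen, and the other alternatives were planned. Elovl6 passed in each of its 19 alternatives, with a log2 change from -6.92 to -5.61 and from -6.69 to -6.19 with 1 mouse left out. The 14 called lists kept their direction in each alternative that was run with camera at the preset correlation, and 13 to 16 lists were called. With an estimated correlation camera called 0 lists, as did fry, so the list calls depend on taking the members as nearly independent. The median change of the SREBP lists lay between -0.81 and -0.61 and that of the acute phase list between 0.31 and 1.08. Signals near background limit dim genes, whose changes are compressed or known only as bounds.

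Genes past the threshold, 2 in all, were 16 with normexp (4 higher, 12 lower), 13 with trend and robust eBayes (3 higher, 10 lower), 6 with probes without a gene symbol, which were the 2 genes and 4 such probes, and 1 each with no filter on dim probes, with well above background required on all 6 arrays (where Usp17la was not tested) and with the slide column. With 1 mouse left out they were 1 to 15, the most without LKO 1 and including Elovl6 each time. At an unadjusted p under 0.05 and at least 1.5-fold there were 416 genes, 206 higher and 210 lower. The cause of these moves was not tested. The replicate block, which rests on shared numbers alone, gave 3 genes (Elovl6, Saa2 and Saa1), a log2 change of -6.51 for Elovl6, adjusted p = 0.0930 for Usp17la and 15 lists, the lymphocyte and neutrophil list being added. Mice with the same number deviated from their group means with correlations of 0.04, -0.05 and -0.07 across genes, and not every mouse correlated best with its own number. A slide block was not run, as there was 1 slide, nor was normexp on mean signals, which the array files used here lack.

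Of the called lists, ChREBP targets (adjusted p = 0.100) and the unfolded protein response (0.0919) lost the call with the slide column, where cytokine (0.882) and macrophage genes (0.754) lost theirs too and interferon-stimulated (5.56e-07, lower) and male-biased genes (3.01e-04, higher) gained one. Erythroid markers lost it with quantile normalization (0.0783), the authors' table (0.0501), no filter on dim probes (0.0739) and array weights (0.0712). The lymphocyte and neutrophil list was called with median scaling (0.0267), normexp (0.0323), no filter (0.0167), all 6 arrays required (0.0354), trend (0.0466) and the block (0.0351).

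Of 109 named genes besides Elovl6, 107 kept their direction in every alternative. The other 2, neither of which passed over all genes, were Ctrl and Hspa5. Ctrl ranged from -0.79 to 0.051 with 1 mouse left out. It turned without control 2, whose log2 value of -0.64 lay above the -2.32 and -2.11 of the other controls. Hspa5 was -0.071 with the slide column, a fit that sets only LKO 1 (6.23) against the controls (mean 6.30).

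Lists that were not called turned in direction under some alternatives, and the cause was not tested. Lipoprotein genes turned with quantile normalization (adjusted p = 0.790), median scaling (0.974), normexp (0.896), no filter (0.857), the replicate block (0.987), the slide column (0.754) and probes without a symbol (0.964), and ranged from 0.423 to 0.984 with 1 mouse left out. Stellate markers turned with normexp (0.896), the authors' table (0.998), no filter (0.857), trend (0.999), array weights (0.637), the replicate block (0.966) and probes without a symbol (0.938), with 0.382 to 0.861 for 1 mouse left out. With the slide column, gluconeogenesis (0.980), insulin signalling (0.931), ATF4 targets (0.115), clock (0.882), fibrosis (0.0105, now called lower) and cell cycle genes (0.0201, now called lower) turned. Insulin signalling and female-biased genes turned when all 6 arrays were required (0.980 each), the latter also with array weights (0.981). Xenobiotic (0.774), cell cycle (0.698) and pancreatic or adipose genes (0.645) turned with no filter. With 1 mouse left out, lists that turned had adjusted p ranges of 0.310 to 0.956 (gluconeogenesis), 0.423 to 0.981 (insulin signalling), 0.254 to 0.999 (ceramide), 0.539 to 0.791 (bile acids), 0.180 to 0.744 (xenobiotic), 0.160 to 0.950 (ATF4), 1.16e-04 to 0.952 (interferon), 2.89e-04 to 0.956 (fibrosis), 0.00890 to 0.984 (cell cycle), 0.222 to 0.984 (clock), 0.480 to 0.990 (female-biased), 0.219 to 0.999 (bile duct) and 0.439 to 0.933 (pancreatic or adipose).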

Other observations

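Some genes passed only with another background correction or variance model, and these were chosen after their values were seen. The fits with normexp and with trend and robust eBayes shared 11 called genes. Among them, Cs, the citrate synthase gene that starts the tricarboxylic acid cycle, was 1.75-fold lower in LKO by the limma fit reported above (adjusted p = 0.100), and Mrap, an accessory protein of the melanocortin receptors, was 1.60-fold lower (adjusted p = 0.100). Upp2, a uridine phosphorylase, was 1.81-fold higher (adjusted p = 0.100). The water channel gene Aqp8, called with normexp and not with trend and robust eBayes, was 2.49-fold lower (adjusted p = 0.104). The groups did not overlap for any of these 4 genes, each of which was well above background on all 6 arrays.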
